A study of Mus musculus and Homo sapiens with 20 samples.

How the data were processed

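RNA-seq was analysed in K562, MEF and HPC-7 cells, with 3 Control and 3 HSP90i libraries in each, and HSP90 ChIP-seq in K562 was analysed as 1 list of peaks. Samples were grouped by their titles, and the count columns named for DMSO, the solvent, were taken as the Control samples of the same line and replicate number. No other columns of sample values were present.

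The RNA-seq values were raw counts per gene as deposited by the authors, whole numbers with a different total in each library. Per the submitters' processing notes, the tools of the series were Trim Galore, TopHat2 2.0.13, Picard, featureCounts, DESeq2, Bowtie2 and MACS2, and the genome builds GRCh37, GRCm38, hg38 and mm10, with no role given to any. The build behind the K562 counts is not given in the sources used here, so no K562 gene positions are reported. The counting's use of strand is not given in the sources used here either, so antisense and overlapping genes could share reads. Near-identical genes such as HSPA1A and HSPA1B could exchange them. The peak list as deposited by the authors held for each peak a score, a fold enrichment (a ratio over the peak caller's background) and the −log10 of its p value. Another column as deposited held the offset of the summit from the peak start, and the column of q values was not used here. Its layout is that of a peak caller's narrow peaks, and its contig names belong to GRCh38. Positions are counted from 1.

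Count tables held 63568 genes for K562 and 43626 for each mouse line, of which 39223, 23179 and 24978 had no count in any library (K562, MEF and HPC-7). Mouse identifiers were checked against a reference table of names, which held 42462 of 43626, with the same symbol for 39092. Mouse gene positions came from GRCm38.p6. No human annotation was used here, so the overlap of peaks with gene starts, which had been planned, was not run.

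Genes were filtered with edgeR's filterByExpr, counts were scaled with TMM, and edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) compared HSP90i with Control within each line, with Benjamini-Hochberg adjustment and a threshold of 0.05. It tested 13456 genes in K562, 12340 in MEF and 11703 in HPC-7. Levels are TMM-scaled CPM. The biological coefficient of variation was 0.172 in K562, 0.0835 in MEF and 0.0900 in HPC-7. The difference between the MEF and HPC-7 responses was tested as the interaction of line and condition over the 12 mouse libraries, in which line and dose cannot be separated. Calls shared between lines were tested with Fisher's exact test, two-sided, across genes.

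The comparisons, 29 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, beside camera with an estimated correlation and fry, each adjusted over the lists of a line. Named genes were, per line, the 8 with the largest change in each direction among called genes with an average log2 CPM of at least 3 and no overlap between groups. Added to these were 13 fixed genes, up to 4 members with the smallest p in each list, 6 genes per direction called in all 3 lines, 5 per sign of the interaction and the 10 strongest peaks. Some genes chosen by these rules are not reported here. Lists of STAT5 and FOXO targets were written after the first results were seen.

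The procedures were tested on simulated data, with 7, 6 and 14 false calls in the K562, MEF and HPC-7 comparisons and 10 in the interaction. These were 5.04%, 3.31%, 7.29% and 3.52% of calls. Counts were drawn independently at each line's trended spread, with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. No shift shared by a whole library was simulated, and far fewer genes were changed than were called in the real data. The shares may therefore not carry over to the real libraries. Of genes changed 1.5-fold, 2-fold and 4-fold, 26.9%, 74.6% and 97.0% were recovered in the simulated K562 comparison (13272 genes), 70.1%, 92.5% and 100% in MEF (11965 genes), and 80.6%, 92.5% and 93.9% in HPC-7 (11314 genes). For the interaction the shares were 45.6%, 90.4% and 98.2% (10355 genes).

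Alternatives were RLE factors, library size alone, upper quartile factors, no filter on low counts, a minimum of 1 CPM in 3 libraries, DESeq2 1.42.0, the replicate number as a block, each library left out in turn, a joint fit of the mouse lines, and stricter thresholds for shared calls. Alternatives added after the data were seen were limma-voom with sample weights, the first principal component of each line's residuals as a covariate, camera on the interaction, and the interaction over genes tested in both lines. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.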

Results

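RNA-seq counts were analysed for 3 cell lines treated with NVP-AUY922, an inhibitor of the ATP-binding site of the HSP90 chaperones, and for their controls. K562 is a human line derived from chronic myeloid leukaemia and carries the BCR-ABL1 fusion kinase. MEF are mouse embryonic fibroblasts, and HPC-7 is a mouse haematopoietic precursor line. Each line had 3 Control and 3 inhibitor-treated (HSP90i) libraries. Treatment lasted 16 h at 300 nM in K562, 200 nM in MEF and 50 nM in HPC-7, so line, species and dose changed together. A list of peaks from HSP90 chromatin immunoprecipitation (ChIP-seq) in K562 came from 1 immunoprecipitated and 1 input library. The series concerns HSP90 in the nucleus, and the RNA comparisons ask which transcripts depend on HSP90 activity in each line.

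Library totals ran from 7936066 to 10950573 counts in K562, from 10542305 to 22872539 in MEF and from 10131491 to 16859394 in HPC-7. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Log2 fold changes are HSP90i over Control with their standard error (SE), levels are CPM (counts scaled to library size) with the SD, and n = 3 per group throughout. In each gene named below as called in a line, all 3 treated values lay beyond all 3 control values of that line.

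In K562, chaperone genes of the heat shock response and the ER rose and immediate early genes fell. HSPA1A, an inducible cytosolic HSP70, went from 24.6 ± 6.09 to 2514 ± 299.7 CPM, a log2 fold change of 6.67 ± 0.23 (adjusted p = 3.39e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its near-identical neighbour HSPA1B rose by 5.74 ± 0.21 (17.4 ± 4.01 to 931 ± 105 CPM), and reads of this pair cannot be assigned with certainty. The HSP110 gene HSPH1 rose by 4.34 ± 0.14, the constitutive HSP70 gene HSPA8 by 3.91 ± 0.13 (284 ± 24.5 to 4273 ± 252 CPM), the J-domain genes DNAJB1 and DNAJB4 by 3.09 ± 0.13 and 2.80 ± 0.26, and the HSP70 co-factor BAG3 by 2.90 ± 0.16. The genes of the drug's targets rose as well, with HSP90AA1 at 3.20 ± 0.13 (523 ± 34.6 to 4820.3 ± 374 CPM), HSP90AB1 at 2.39 ± 0.13 and the endoplasmic reticulum (ER) form HSP90B1 at 1.39 ± 0.12. The mitochondrial form TRAP1 was not called (−0.26 ± 0.17, adjusted p = 0.367), nor was HSF1, the heat shock transcription factor (−0.14 ± 0.19, adjusted p = 0.688), nor HCFC1, a chromatin co-regulator (0.17 ± 0.14, adjusted p = 0.477), by the same edgeR test.

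The largest decreases in K562 were in CISH, a cytokine-signalling inhibitor, which fell from 75.9 ± 6.49 to 3.05 ± 0.652 CPM (log2 fold change −4.62 ± 0.19), and in the immediate early transcription factor gene EGR1 (−4.12 ± 0.17). ID3 changed by −3.76 ± 0.18, SOCS2 by −3.51 ± 0.13, APOL4 by −3.36 ± 0.17, PHLDA1 by −3.24 ± 0.18 and CYP1A1 by −3.11 ± 0.13. The kinase gene PIM1 was abundant in the controls and changed by −3.25 ± 0.12 (2298 ± 85.5 to 241 ± 9.52 CPM). MYC, a growth-promoting transcription factor gene, fell from 251 ± 36.8 to 93.4 ± 6.32 CPM (−1.43 ± 0.15, adjusted p = 0.00103 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The adjusted p of the 8 largest decreases ranged from 3.39e-06 for PIM1 to 2.94e-05 for PHLDA1.

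Of the 26 tested members of the heat shock list, 26 rose in K562 and 0 fell, with the same count adjusted over the list alone (median 2.38, camera adjusted p = 7.79e-37, adjusted p = 0.0454 with an estimated correlation). The ER chaperone and ER-associated degradation list had 17 of 22 higher and 0 lower, or 20 higher and 0 lower adjusted over the list alone (median 1.15, camera adjusted p = 5.08e-17, adjusted p = 0.0339 with an estimated correlation). Its members included HERPUD1 (1.93 ± 0.11), HSPA5, the main HSP70 of the ER (1.77 ± 0.13), and the disulfide isomerase gene PDIA4 (1.45 ± 0.12). The immediate early list, of genes that respond to growth signals, had 2 of 17 higher and 14 lower, the same adjusted over the list alone (median −1.60, camera adjusted p = 3.99e-11, adjusted p = 0.0339 with an estimated correlation). Its lower members included SPRY4 (−2.78 ± 0.18) and CCND1, which encodes cyclin D1 (−1.80 ± 0.14). These 3 lists held with an estimated correlation, and no other list did.

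Genes of G2/M and mitosis in K562 had 13 of 52 higher and 0 lower, or 24 higher and 0 lower adjusted over the list alone (median 0.41, camera adjusted p = 8.53e-11, adjusted p = 0.152 with an estimated correlation). Examples were CKS2 (1.15 ± 0.16) and the centromeric histone gene CENPA (0.91 ± 0.13). Ribosome biogenesis had 0 of 21 higher and 8 lower, or 0 higher and 10 lower adjusted over the list alone (median −0.45, camera adjusted p = 3.14e-06, adjusted p = 0.103 with an estimated correlation), with PPAN at −1.57 ± 0.25. G1/S and DNA replication had 0 of 42 higher and 3 lower, or 1 higher and 10 lower adjusted over the list alone (median −0.28, camera adjusted p = 0.000103, adjusted p = 0.391 with an estimated correlation). Its called member MCM6, a subunit of the replicative helicase (−0.64 ± 0.11), lost its call without HSP90i replicate 1, 2 or 3 (adjusted p = 0.0879, 0.0582 and 0.0800, edgeR's quasi-likelihood test). HSP90 co-chaperones had 7 of 25 higher and 0 lower, or 10 higher and 0 lower adjusted over the list alone (median 0.11, camera adjusted p = 0.00175, adjusted p = 0.489 with an estimated correlation), led by CHORDC1 (2.48 ± 0.16) and FKBP4 (2.16 ± 0.16). Both genes, with AHSA1, PTGES3 and STIP1, were also on the heat shock list, whose tested members all rose. Most higher calls of the co-chaperone list thus repeat that result. Interferon-stimulated genes had 5 of 12 higher and 1 lower, or 6 higher and 1 lower adjusted over the list alone (median 0.65, camera adjusted p = 0.0117, adjusted p = 0.156 with an estimated correlation), with BST2 at 1.94 ± 0.28 and RSAD2 at −1.19 ± 0.15.

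Cholesterol synthesis and uptake in K562 had 5 of 20 higher and 0 lower, the same adjusted over the list alone (median 0.32, camera adjusted p = 0.00979, adjusted p = 0.156 with an estimated correlation), with HMGCS1, an early enzyme of the pathway, at 1.10 ± 0.14. Autophagy and lysosome genes had 2 of 19 higher and 0 lower, or 3 higher and 0 lower adjusted over the list alone (median 0.26, camera adjusted p = 0.00979, adjusted p = 0.499 with an estimated correlation). That list lost its call without Control replicate 2 (adjusted p = 0.0757) or Control replicate 3 (adjusted p = 0.0565). The ATF4-CHOP stress list was not called (4 higher and 0 lower of 22, median 0.13, camera adjusted p = 0.0510, or 5 higher and 1 lower adjusted over the list alone) but was without Control replicate 1 (adjusted p = 0.00120) or HSP90i replicate 3 (adjusted p = 0.0304). Cytosolic ribosomal proteins had 0 calls among 74, also when adjusted over the list alone (median −0.08, camera adjusted p = 0.975). Their per-library medians were 0.51 in Control replicate 1 against −0.18 and −0.30 in the other controls. The list median was 0.24 without Control replicate 1 (adjusted p = 5.98e-09) and −0.23 without Control replicate 3 (adjusted p = 0.0346). Proteasome subunits (0 of 31 called, camera adjusted p = 0.405) and mitochondrially encoded mRNAs (0 of 13, camera adjusted p = 0.285) were called higher without Control replicate 1 (adjusted p = 0.000361 and 0.00200). So were the epithelial markers (adjusted p = 0.0168 without that library, against 0.405 with it, 0 of 5 called). In Control replicate 1 the medians of the mitochondrial, proteasome and epithelial lists were 0.42, 0.26 and 0.56, relative to the mean of the controls, and none of these 3 lists had a call adjusted over the list alone.

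The remaining lists were not called by camera in K562. HCFC1 and its partners had 0 higher and 1 lower of 19, median 0.05, camera adjusted p = 0.975. The p53 targets had 1 higher and 2 lower of 14, median 0.11, camera adjusted p = 0.975, with AEN at −0.97 ± 0.12 and GDF15 at −1.29 ± 0.19. Glycolysis and hypoxia had 3 higher and 0 lower of 17, median −0.03, camera adjusted p = 0.358, with the collagen-modifying enzyme gene P4HA1 at 1.22 ± 0.13, and the NRF2 list had 4 higher and 0 lower of 14, median 0.08, camera adjusted p = 0.0858. Erythroid genes had 1 higher and 1 lower of 23, median −0.06, camera adjusted p = 0.975, with EPB42, a red cell membrane protein gene, at 3.13 ± 0.43. The mast cell list had 0 higher and 1 lower of 5, median 0.25, camera adjusted p = 0.975, its called member being GATA2 (−1.85 ± 0.12). Megakaryocyte markers had 0 higher and 1 lower of 5, median 0.02, camera adjusted p = 0.975, myeloid markers 0 higher and 0 lower of 8, median −0.11, camera adjusted p = 0.975, fibroblast matrix genes 1 higher and 0 lower of 7, median −0.06, camera adjusted p = 0.975 and SRF and YAP targets 0 higher and 1 lower of 12, median 0.22, camera adjusted p = 0.490, with TAGLN at −1.72 ± 0.18. Adjusted over the list alone, these counts were the same for HCFC1 partners and for erythroid, myeloid, fibroblast and SRF and YAP genes. They were 2 higher and 3 lower for p53 targets, 4 higher and 2 lower for glycolysis, 5 higher and 0 lower for NRF2, and 1 higher and 1 lower for both the mast cell and megakaryocyte lists. The median and the camera direction differed in sign for glycolysis, ribosomal proteins and fibroblast matrix genes, the first having a median of −0.03 and a mean of 0.18. The p53 targets had a median above 0 and a mean of −0.05. Meanwhile fry's direction was opposite to camera's for HCFC1 partners, p53 targets, ribosomal proteins, erythroid genes and the mast cell list.

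By edgeR's quasi-likelihood test 688 genes were higher and 803 lower in K562 among 13456 tested, 225 and 418 of them at least 2-fold. Treated and control values did not overlap in 35.2% of tested genes, where chance gives 10% on average over all splits of the libraries. Genes that move together within a library can put a single split far from that average. The counts depended on single libraries and were 1922 higher and 1995 lower without Control replicate 1, 241 and 328 without Control replicate 2, 173 and 183 without HSP90i replicate 1, 177 and 171 without HSP90i replicate 2, and 202 and 216 without HSP90i replicate 3. Scaling by library size alone gave 435 higher and 1195 lower, 26.7% higher against 46.1% in the main scaling and a median of all genes of −0.13, and upper quartile factors gave 535 and 981.

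**Figure D1:**
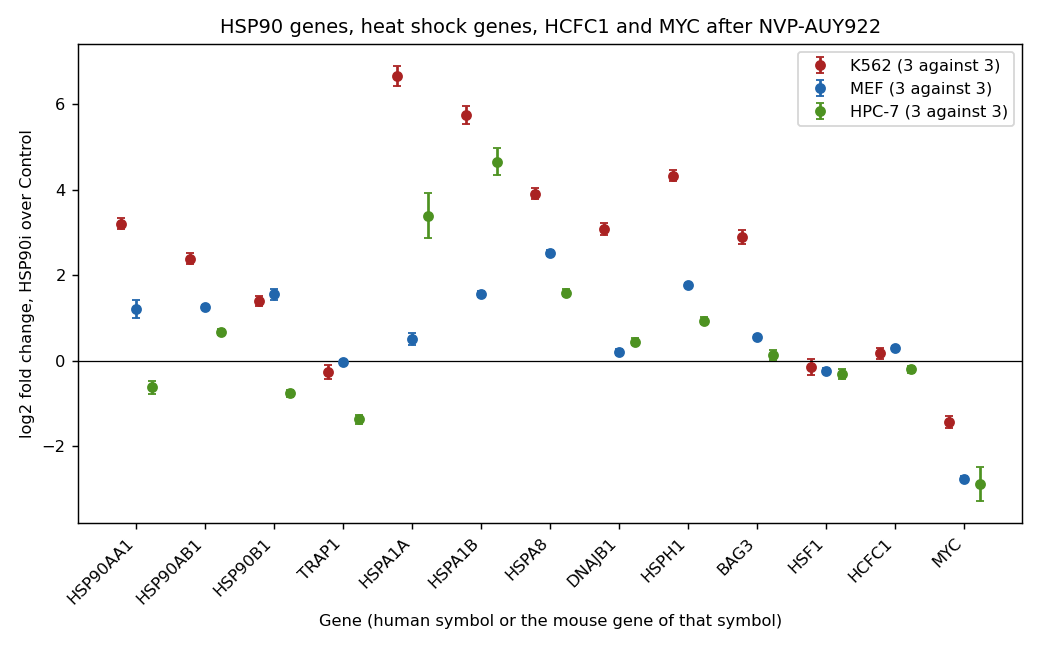
Log2 fold change of HSP90i over Control (y axis) for 13 genes fixed in advance (x axis), with points for the estimate in each cell line and bars for its SE, from 3 against 3 libraries. HSP90AA1 lay at 3.20 in K562, 1.21 in MEF and −0.62 in HPC-7, and MYC lay below 0 in all 3 lines.

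In MEF, 73.4% of tested genes were called, and camera at the preset correlation called the cell cycle, SRF and YAP cytoskeletal and immediate early lists lower. With an estimated correlation none of these held (adjusted p = 0.0961 for G1/S, 0.184 for G2/M, 0.294 for SRF and YAP targets and 0.182 for immediate early genes). That correlation came from 3 libraries per group. The rotation test fry asks whether a list moves on balance, not whether it moves more than other genes. It gave adjusted p = 1.82e-06, 6.43e-06, 7.39e-06 and 4.55e-06 in that order. Ctgf, a secreted matricellular protein gene driven by YAP and SRF, fell from 269 ± 7.38 to 7.18 ± 0.559 CPM (log2 fold change −5.24 ± 0.07, adjusted p = 2.77e-09, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Sema7a changed by −5.31 ± 0.12, Tnfrsf12a by −4.96 ± 0.09, Id3 by −4.49 ± 0.07, the chemokine gene Cxcl1 by −4.49 ± 0.14, Fbxo5 by −4.47 ± 0.11 and Klf2 by −4.44 ± 0.22. The largest increases were in genes low in the controls. Inmt went from 0.124 ± 0.0566 to 20.9 ± 1.02 CPM, Gng4 from 0.812 ± 0.180 to 40.3 ± 1.21 CPM and Aldh3a1, an aldehyde dehydrogenase gene, from 1.12 ± 0.0749 to 43.2 ± 0.146 CPM, while Gfra1, which encodes a receptor subunit for GDNF, went from 9.51 ± 0.711 to 244 ± 8.75 CPM (log2 fold change 4.69 ± 0.07). Gprc5c rose by 4.92 ± 0.19, Capn6 by 4.42 ± 0.14, Kank3 by 4.40 ± 0.14 and Tspan13 by 4.38 ± 0.20.

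Several HSP70 and HSP90 genes rose in MEF. Hspa8 changed by 2.52 ± 0.07 (1596 ± 90.6 to 9158 ± 598 CPM), Hsph1 by 1.78 ± 0.05, Hspa1b, which shares near-identical sequence with Hspa1a, by 1.56 ± 0.07 and Bag3 by 0.56 ± 0.05. Hsp90aa1 rose by 1.21 ± 0.22 (684 ± 208 to 1579 ± 239.9 CPM), Hsp90ab1 by 1.25 ± 0.05 and Hsp90b1 by 1.56 ± 0.13. In the GRCm38.p6 annotation, Hsp90aa1 (ENSMUSG00000021270) lies on chromosome 12 (110691036 to 110696395), Hsp90ab1 (ENSMUSG00000023944) on chromosome 17 (45567778 to 45573261), Hsp90b1 (ENSMUSG00000020048) on chromosome 10 (86690841 to 86705444), Hspa8 on chromosome 9 (40801276 to 40805202) and Myc on chromosome 15 (61985341 to 61990361). Hcfc1 rose by 0.30 ± 0.04 (adjusted p = 0.00018) and Myc changed by −2.76 ± 0.07 (79.9 ± 1.73 to 11.9 ± 0.902 CPM, adjusted p = 1.34e-08), both by edgeR's quasi-likelihood test. Trap1 was not called (−0.03 ± 0.05, adjusted p = 0.577). Small changes in Hspa1a (0.51 ± 0.14), Dnajb1 (0.21 ± 0.07) and Hsf1 (−0.23 ± 0.05) passed edgeR's test, but Hspa1a did not with DESeq2 (adjusted p = 0.0602) and Hsf1 did not with upper quartile factors (adjusted p = 0.0598) or in the fit over 12 mouse libraries (adjusted p = 0.277). Dnajb1 lost its call without Control replicate 2 (adjusted p = 0.0535) and without HSP90i replicate 1 or 2 (adjusted p = 0.0557 and 0.0675).

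Cell cycle lists fell in MEF. G1/S and DNA replication had 0 of 42 higher and 41 lower, the same adjusted over the list alone (median −1.90, camera adjusted p = 7.47e-13, adjusted p = 0.0961 with an estimated correlation), with the ribonucleotide reductase gene Rrm2 at −3.62 ± 0.08 and Uhrf1 at −3.13 ± 0.08. G2/M and mitosis had 1 of 52 higher and 49 lower, or 1 higher and 51 lower adjusted over the list alone (median −1.94, camera adjusted p = 3.62e-13, adjusted p = 0.184 with an estimated correlation), with Birc5 at −3.20 ± 0.06 and the anaphase activator gene Cdc20 at −2.35 ± 0.05. Ribosome biogenesis had 0 of 21 higher and 20 lower, the same adjusted over the list alone (median −1.73, camera adjusted p = 9.75e-08, adjusted p = 0.0745 with an estimated correlation), with the nucleolar protein gene Nop56 at −2.18 ± 0.06. Immediate early genes had 2 of 20 higher and 18 lower, the same adjusted over the list alone (median −2.56, camera adjusted p = 3.14e-06, adjusted p = 0.182 with an estimated correlation), with Egr1 at −4.15 ± 0.10 and Fosl1 at −3.66 ± 0.10. SRF and YAP targets had 1 of 17 higher and 14 lower, the same adjusted over the list alone (median −1.12, camera adjusted p = 0.000368, adjusted p = 0.294 with an estimated correlation), with Cyr61 at −3.50 ± 0.10 and smooth muscle actin, Acta2, at −1.25 ± 0.04. Cholesterol synthesis and uptake had 0 of 20 higher and 19 lower, the same adjusted over the list alone (median −1.13, camera adjusted p = 1.40e-06, adjusted p = 0.184 with an estimated correlation), with Sqle, the squalene epoxidase gene, at −1.48 ± 0.04. The ATF4-CHOP stress list had 5 of 22 higher and 14 lower, the same adjusted over the list alone (median −1.13, camera adjusted p = 0.0225, adjusted p = 0.200 with an estimated correlation), with the asparagine synthetase gene Asns at −1.92 ± 0.05, Trib3 at −3.67 ± 0.10 and Sesn2 at 1.82 ± 0.05.

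Lists that rose in MEF were led by the heat shock response, with 25 of 30 higher and 3 lower, the same adjusted over the list alone (median 0.71, camera adjusted p = 1.68e-05, adjusted p = 0.0961 with an estimated correlation). The small heat shock protein gene Hspb1 changed by 2.60 ± 0.08. Autophagy and lysosome genes had 17 of 20 higher and 2 lower, the same adjusted over the list alone (median 0.54, camera adjusted p = 0.000306, adjusted p = 0.294 with an estimated correlation), with Map1lc3b, which encodes a component of autophagosome membranes, at 1.14 ± 0.05. The p53 targets had 9 of 14 higher and 3 lower, the same adjusted over the list alone (median 0.62, camera adjusted p = 0.0293, adjusted p = 0.190 with an estimated correlation), with the cyclin-dependent kinase inhibitor gene Cdkn1a at 1.57 ± 0.08 and Btg2 at 1.70 ± 0.06. Cytosolic ribosomal proteins had 38 of 73 higher and 1 lower, the same adjusted over the list alone (median 0.14, camera adjusted p = 0.00186, adjusted p = 0.519 with an estimated correlation), with Rps27 at 0.40 ± 0.05. No MEF list held with an estimated correlation.

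Other MEF lists were not called, although many members moved in both directions. Fibroblast matrix genes had 11 higher and 8 lower of 22, median 0.19, camera adjusted p = 0.454, with the collagen gene Col3a1 at 1.16 ± 0.04 and Loxl1 at −1.37 ± 0.05. ER chaperones had 10 higher and 5 lower of 21, median 0.11, camera adjusted p = 0.232, with Pdia3 at 1.12 ± 0.06, and HSP90 co-chaperones had 9 higher and 13 lower of 25, median −0.23, camera adjusted p = 0.532, with Ahsa1 at 0.95 ± 0.04 and Fkbp5 at −2.69 ± 0.10. HCFC1 and its partners had 4 higher and 8 lower of 19, median −0.04, camera adjusted p = 0.452, proteasome subunits 8 higher and 10 lower of 31, median 0.01, camera adjusted p = 0.824 and interferon-stimulated genes 5 higher and 2 lower of 12, median 0.11, camera adjusted p = 0.232. Glycolysis and hypoxia had 5 higher and 10 lower of 18, median −0.35, camera adjusted p = 0.276, with hexokinase 2, Hk2, at −3.42 ± 0.11, and the NRF2 list had 4 higher and 9 lower of 16, median −0.43, camera adjusted p = 0.123. Erythroid genes had 1 higher and 5 lower of 7, median −0.63, camera adjusted p = 0.142, megakaryocyte genes 1 higher and 4 lower of 6, median −0.85, camera adjusted p = 0.276 and mitochondrially encoded mRNAs 4 higher and 0 lower of 11, median 0.28, camera adjusted p = 0.185. Adjusted over the list alone, fibroblast genes had 12 higher and 8 lower, interferon-stimulated genes had 5 higher and 1 lower, and the rest had these same counts. The treated mitochondrial medians relative to the controls were 0.14, 0.12 and 0.60, with Control replicate 2 at 0.12, so HSP90i replicate 3 stood apart. The proteasome median lay above 0, while its mean (−0.05) and camera direction lay below.

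In total, edgeR's quasi-likelihood test called 4337 genes higher and 4720 lower of 12340 tested in MEF, with 1379 and 1614 at least 2-fold. Values did not overlap between the groups in 76.2% of tested genes, where chance gives 10% on average over all splits. Upper quartile factors moved the median of all genes from −0.01 to 0.09 and gave 5037 higher and 4072 lower. Fitted with the HPC-7 libraries, the median over all MEF genes was 0.10 and the counts were 5166 higher and 3983 lower.

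In HPC-7, camera at the preset correlation called cell cycle, cholesterol and ER chaperone lists lower and megakaryocyte and myeloid lists higher. With an estimated correlation none of these calls held (adjusted p = 0.424 for each). That correlation came from 3 libraries per group and was 0.821 for G1/S, where HSP90i replicate 2 stood apart. By fry the adjusted p was 0.00275 for G1/S, 0.000617 for G2/M and 0.000596 for myeloid genes. It was 0.000366 for the cholesterol, ER chaperone and megakaryocyte lists. Genes low in the controls had the largest increases. The phosphatase gene Ptpn14 went from 0.104 ± 0.0563 to 19.8 ± 1.61 CPM, a log2 fold change of 7.52 ± 0.26 (adjusted p = 6.08e-08, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The oxysterol receptor gene Gpr183 went from 0.118 ± 0.204 to 19.0 ± 1.88 CPM, with its control counts all in Control replicate 1, Colec11 from 0.407 ± 0.156 to 49.0 ± 7.84 CPM and Bmf, which encodes a pro-apoptotic BCL2-family protein, from 0.501 ± 0.236 to 29.9 ± 4.14 CPM. Mycl rose by 6.37 ± 0.30, Muc6 by 5.86 ± 0.25, the coagulation factor gene F10 by 5.07 ± 0.31 and Cpz by 5.07 ± 0.15. The largest decreases were in the fatty acid desaturase gene Scd1 (−4.26 ± 0.28), Etv4 (−4.23 ± 0.52), Etv5 (−4.13 ± 0.56), Gem (301 ± 4.24 to 19.6 ± 16.7 CPM), the thymidine kinase gene Tk1 (−3.90 ± 0.46), Rmi2 (−3.83 ± 0.40), Iqgap3 (−3.83 ± 0.38) and Parm1 (−3.82 ± 0.14).

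Chaperone genes moved in both directions in HPC-7. Hspa8 changed by 1.60 ± 0.08 (1314 ± 58.5 to 3970.0 ± 179.8 CPM) and Hsph1 by 0.94 ± 0.08. Hspa1b rose from a low level (0.771 ± 0.0768 to 19.7 ± 6.89 CPM), as did its near-identical copy Hspa1a (0.135 ± 0.0870 to 1.67 ± 0.769 CPM). Hsp90ab1 changed by 0.67 ± 0.08, while Hsp90aa1 changed by −0.62 ± 0.15 (673 ± 19.4 to 437 ± 113 CPM, adjusted p = 0.00345), Hsp90b1 by −0.76 ± 0.08 (adjusted p = 1.92e-05) and Trap1 by −1.37 ± 0.10 by edgeR's quasi-likelihood test. Dnajb1 changed by 0.44 ± 0.08 and Myc by −2.89 ± 0.40 (240.2 ± 6.62 to 32.9 ± 25.8 CPM). Bag3 was not called (0.14 ± 0.11, adjusted p = 0.282). Hsf1 (−0.31 ± 0.11, adjusted p = 0.0312) and Hcfc1 (−0.20 ± 0.07, adjusted p = 0.0322) passed edgeR's test. With upper quartile factors neither did (adjusted p = 0.0681 and 0.0971). Without Control replicate 2, Control replicate 3 or HSP90i replicate 3 the adjusted p was 0.0762, 0.0827 and 0.0617 for Hsf1 and 0.128, 0.0969 and 0.0944 for Hcfc1. Hsf1 was also lost without Control replicate 1 (adjusted p = 0.0639).

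All 42 tested G1/S and DNA replication genes fell in HPC-7, the same adjusted over the list alone (median −2.49, camera adjusted p = 8.24e-10, adjusted p = 0.424 with an estimated correlation), with the replication licensing inhibitor gene Gmnn at −2.30 ± 0.15 and Gins2 at −2.79 ± 0.22. In HSP90i replicate 2 the list median relative to the controls was −1.80, against −2.96 and −3.00 in the other treated libraries. G2/M and mitosis had 2 of 52 higher and 50 lower, the same adjusted over the list alone (median −1.53, camera adjusted p = 6.74e-12, adjusted p = 0.424 with an estimated correlation), with Cdca3 at −2.44 ± 0.13 and treated medians of −1.73, −1.27 and −1.64. Ribosome biogenesis had 0 of 21 higher and 21 lower, the same adjusted over the list alone (median −1.53, camera adjusted p = 7.19e-07, adjusted p = 0.424 with an estimated correlation), with the nucleolar methyltransferase gene Fbl at −1.74 ± 0.13 and treated medians of −1.69, −1.22 and −1.80. Cholesterol synthesis and uptake had 0 of 19 higher and 19 lower, the same adjusted over the list alone (median −1.99, camera adjusted p = 3.48e-08, adjusted p = 0.424 with an estimated correlation), with the farnesyl diphosphate synthase gene Fdps at −2.97 ± 0.13 and Cyp51 at −2.89 ± 0.14.

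ER chaperones in HPC-7 had 4 of 21 higher and 15 lower, or 5 higher and 15 lower adjusted over the list alone (median −0.69, camera adjusted p = 0.00612, adjusted p = 0.424 with an estimated correlation), with Hspa5 at −1.45 ± 0.12 and Pdia6 at −1.37 ± 0.08. Proteasome subunits had 0 of 31 higher and 29 lower, the same adjusted over the list alone (median −0.68, camera adjusted p = 7.20e-08, adjusted p = 0.424 with an estimated correlation), with Psmd14 at −0.97 ± 0.09. HSP90 co-chaperones had 6 of 25 higher and 16 lower, the same adjusted over the list alone (median −0.49, camera adjusted p = 0.0303, adjusted p = 0.443 with an estimated correlation), with the AAA ATPase gene Ruvbl1 at −1.10 ± 0.08. Glycolysis and hypoxia had 3 of 17 higher and 11 lower, the same adjusted over the list alone (median −1.15, camera adjusted p = 0.0303, adjusted p = 0.424 with an estimated correlation), with enolase 1, Eno1, at −1.58 ± 0.10. Among lists that rose, megakaryocyte markers had 13 of 15 higher and 2 lower, the same adjusted over the list alone (median 1.06, camera adjusted p = 0.00344, adjusted p = 0.424 with an estimated correlation), with the integrin gene Itga2b at 1.68 ± 0.09, Vwf at 2.62 ± 0.16 and Pf4 at −1.17 ± 0.08. Myeloid markers had 9 of 14 higher and 1 lower, the same adjusted over the list alone (median 0.68, camera adjusted p = 0.0280, adjusted p = 0.424 with an estimated correlation), with the integrin gene Itgam at 2.67 ± 0.10 and Lyz2 at 1.05 ± 0.09. Autophagy and lysosome genes had 12 of 19 higher and 0 lower, the same adjusted over the list alone (median 0.69, camera adjusted p = 0.00281, adjusted p = 0.424 with an estimated correlation), with Ulk1, an autophagy-initiating kinase gene, at 1.51 ± 0.08. The p53 targets had 9 of 13 higher and 1 lower, the same adjusted over the list alone (median 0.52, camera adjusted p = 0.0411, adjusted p = 0.424 with an estimated correlation), with Bbc3 at 1.90 ± 0.16, but were not called without HSP90i replicate 2 (adjusted p = 0.113). No HPC-7 list held with an estimated correlation.

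The heat shock list was not called in HPC-7 (12 higher and 8 lower of 25, median 0.14, camera adjusted p = 0.205), and its members went both ways, with Hsp90aa1 lower and the haem oxygenase gene Hmox1 at 3.14 ± 0.22 and Dedd2 at 1.58 ± 0.11. The rotation test fry, which asks only whether a list moves on balance, gave adjusted p = 0.00108 for it, against 2.72e-05 in K562 and 1.81e-06 in MEF. Immediate early genes had 3 higher and 8 lower of 14, median −0.94, camera adjusted p = 0.205, with the phosphatase gene Dusp4 at −2.53 ± 0.20 and Ier3 at 1.18 ± 0.14, and were called without HSP90i replicate 2 (adjusted p = 0.0243). Erythroid genes had 8 higher and 2 lower of 12, median 0.49, camera adjusted p = 0.107, with Gata1 at 2.21 ± 0.12 and the transferrin receptor gene Tfrc at −3.14 ± 0.30. The mast cell list had 2 higher and 2 lower of 7, median 0.10, camera adjusted p = 0.624, with Kit at 1.35 ± 0.08. The ATF4-CHOP list had 5 higher and 8 lower of 14, median −0.49, camera adjusted p = 0.624, with Ddit3, which encodes CHOP, at 1.82 ± 0.11 and Psat1 at −0.97 ± 0.08. HCFC1 and its partners had 2 higher and 9 lower of 19, median −0.15, camera adjusted p = 0.205, with Ogt at 1.30 ± 0.08 and E2f1 going from 53.8 to 19.1 CPM. Interferon-stimulated genes had 5 higher and 2 lower of 9, median 0.57, camera adjusted p = 0.251, ribosomal proteins 16 higher and 7 lower of 73, median 0.08, camera adjusted p = 0.431, the NRF2 list 4 higher and 5 lower of 13, median 0.11, camera adjusted p = 0.962, SRF and YAP targets 2 higher and 2 lower of 8, median −0.02, camera adjusted p = 0.967 and mitochondrially encoded mRNAs 1 higher and 3 lower of 11, median −0.23, camera adjusted p = 0.598. Adjusted over the list alone, HCFC1 partners had 2 higher and 8 lower, ribosomal proteins had 11 higher and 6 lower, and the others had these same counts. The treated mitochondrial medians relative to the controls were −1.03, −0.16 and 0.32, so the libraries went in both directions and HSP90i replicate 1 stood apart. Median and camera direction differed in sign for the NRF2 list and for SRF and YAP targets, whose mean was 0.23.

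By edgeR's quasi-likelihood test 4273 genes were higher and 4284 lower of 11703 tested in HPC-7, with 1464 and 1604 at least 2-fold. Values did not overlap between the groups in 77.4% of tested genes, where chance gives 10% on average over all splits. HSP90i replicate 2 lay nearer to the controls on the first principal component (38.7, against 63.1 and 64.8), and without it 4358 genes were higher and 4423 lower.

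**Figure D2:**
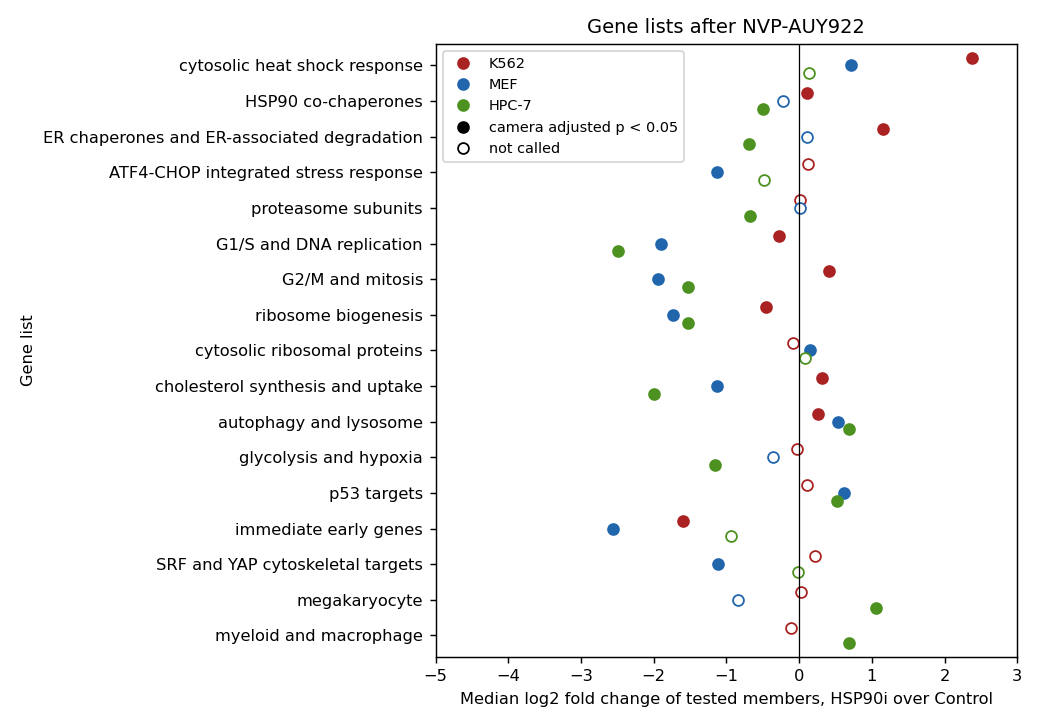
Median log2 fold change of the tested members (x axis) of 17 gene lists (y axis) in each cell line, with filled points where camera's adjusted p passed the threshold at the preset correlation. G2/M and mitosis lay at 0.41 in K562, −1.94 in MEF and −1.53 in HPC-7.

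Most lists of other cell types had too few tested members for a test. Muscle markers had 3 tested genes in K562, 2 in MEF and 0 in HPC-7. Epithelial markers had 3 in MEF and 0 in HPC-7. Endothelial markers had 3 in K562, 1 in MEF and 4 in HPC-7, neuronal and glial markers 2, 4 and 1, and lymphocyte markers 4, 0 and 2. Myeloid and mast cell lists had 4 and 1 tested genes in MEF, and the fibroblast list had 1 in HPC-7.

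The lines were then compared to ask which responses they shared. MEF and HPC-7 shared 2063 genes called higher, against 1193 for independent lists, and 2709 called lower, against 1594, among 10371 genes tested in both (odds ratios 5.28 and 7.27, two-sided Fisher's exact test p = 7.32e-313 for the higher genes). Fisher's test takes genes as independent, which they are not, so its p-values for shared calls can be too small. Of 5912 genes called in both, 1140 moved in opposite directions. Across genes, which are not independent replicates, the fold changes of these lines had a Pearson r of 0.55 and a Spearman rho of 0.56.

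Human and mouse genes were matched by identical symbols, and higher and lower calls were each set against independent lists. The same limit of Fisher's test holds for the p-values of this comparison. K562 and MEF shared 266 higher genes (178 for independent lists, Fisher's exact test p = 4.64e-16) and 246 lower genes (179, p = 3.29e-11), with 283 of 795 moving in opposite directions. K562 and HPC-7 shared 229 higher genes (179 for independent lists, Fisher's exact test p = 2.58e-06) and 190 lower genes (158, p = 0.000857), with 295 of 714 moving in opposite directions. With calls at the stricter adjusted p of 0.01, the lower genes of K562 and HPC-7 shared 55 genes (45.7 for independent lists, odds ratio 1.37 against 1.42 in the main calls), and Fisher's exact test gave p = 0.0934. At 2-fold or more they shared 35 (20.8 for independent lists, Fisher's exact test p = 0.00171). Pearson's r was 0.16 and Spearman's rho 0.16 across genes for K562 and MEF, and 0.12 and 0.16 for K562 and HPC-7.

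In all 3 lines 159 genes were called higher, against 54.5 for independent lists, and 136 lower, against 60.9, among 8322 genes. The ubiquitin ligase gene FBXO32 rose by 2.11 in K562, 3.35 in MEF and 2.06 in HPC-7. DEDD2 rose by 2.38, 2.52 and 1.58 in that order, beside HSPA8 and HSPA1B. The protease gene MMP19 rose by 1.51 and 1.60 in K562 and MEF, and from 0.285 to 1.10 CPM in HPC-7. The repressor gene HBP1 rose by 1.55 and 1.66, and was called higher in HPC-7, at 269.8 CPM after treatment. ID1, a differentiation inhibitor gene, fell in each line (−3.31, −3.60 and −2.28), as did CCND1 (−1.80, −2.06 and −2.88), PLK3 (−1.64, −1.52 and −3.24), MYC and the ribosome assembly gene RRS1 (−1.48, −2.03 and −1.36). TRMT61A (−1.47, −2.79 and −1.96) lost its K562 call without HSP90i replicate 1, 2 or 3 (edgeR adjusted p = 0.0612, 0.103 and 0.0937).

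**Figure D3:**
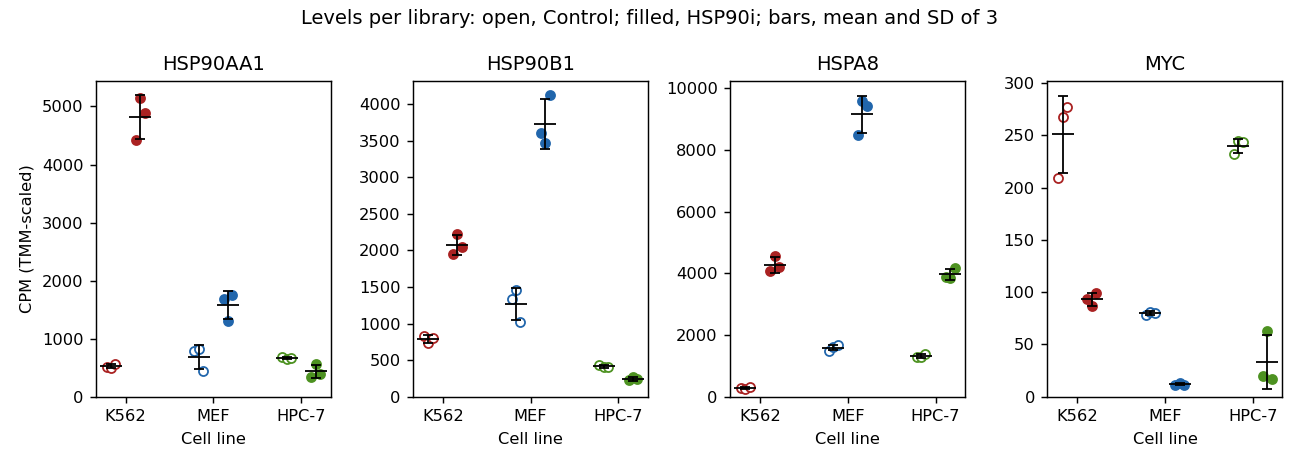
TMM-scaled CPM (y axis) of HSP90AA1, HSP90B1, HSPA8 and MYC or their mouse counterparts in each library of the 3 cell lines (x axis), open for Control and filled for HSP90i, with bars for the mean and SD of 3. HSP90B1 went from 792 to 2078 CPM in K562, 1269.6 to 3733 CPM in MEF and 415 to 245 CPM in HPC-7.

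The responses of MEF and HPC-7 were tested against each other as an interaction of line and condition. In the joint TMM scaling the median difference over genes tested in both lines was 0.13, against 0.005 with RLE factors. The gene differences in this joint scaling may include a shift of about that size towards MEF, which weighs most on small ones. No call among the 23 genes named for the interaction changed under settings other than a left-out library. Hsp90b1 differed by 2.44 ± 0.15 (log2, MEF minus HPC-7, adjusted p = 3.00e-08 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), having risen in MEF and fallen in HPC-7. Hsp90aa1 also went in opposite directions (difference 1.95 ± 0.28, adjusted p = 6.71e-05). Hcfc1 differed by 0.62 ± 0.09, with a rise in MEF and a fall in HPC-7 that was lost under several settings (adjusted p = 0.0971 with upper quartile factors and 0.0826 with the replicate block, edgeR's quasi-likelihood test). It is a gene on chromosome X (73942792 to 73966995, GRCm38.p6). Hspa8 (1.04 ± 0.10) and Hsph1 (0.96 ± 0.10) rose more in MEF, and Hspa1b (−2.98 ± 0.35) and Hspa1a (−2.76 ± 0.54) rose more in HPC-7, where their control levels were low. Trap1 differed by 1.45 ± 0.13 and Hsp90ab1 by 0.70 ± 0.09. Bag3 differed by 0.54 ± 0.12, and this call was lost without HPC-7 Control replicate 1, 2 or 3 (adjusted p = 0.0544, 0.0680 and 0.102). The responses of Hsf1 (0.19 ± 0.13, adjusted p = 0.274), Dnajb1 (−0.11 ± 0.12, adjusted p = 0.488) and Myc (0.25 ± 0.48, adjusted p = 0.745) were not called different by edgeR. Without HPC-7 Control replicate 3 Dnajb1 was called (adjusted p = 0.0411), and without HPC-7 HSP90i replicate 2 Myc was (difference 1.09, adjusted p = 2.85e-06).

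Over genes tested in both lines, 7 lists differed by camera at the preset correlation, and none with an estimated correlation, where the lowest adjusted p was 0.138. These list values used TMM factors computed over those genes alone, not the joint scaling above. With RLE factors the medians lay slightly higher (0.57 for heat shock and −0.25 for G2/M, against 0.51 and −0.32 here). The MEF response lay above that of HPC-7 in heat shock genes (16 of 25 above and 5 below, median difference 0.51, camera adjusted p = 0.00467), ER chaperones (14 of 21 above and 1 below, median difference 0.70, camera adjusted p = 5.01e-06), proteasome subunits (27 of 31 above and 1 below, median difference 0.55, camera adjusted p = 1.13e-08) and cholesterol genes (14 of 19 above and 0 below, median difference 0.72, camera adjusted p = 9.78e-06). It also lay above in glycolysis and hypoxia (9 of 16 above and 2 below, median difference 0.34, camera adjusted p = 0.0376). It lay below in G2/M and mitosis (2 of 52 above and 21 below, median difference −0.32, camera adjusted p = 0.0464) and in SRF and YAP targets (7 of 8 below, median difference −1.11, camera adjusted p = 0.000875). Adjusted over the list alone, ER chaperones had 15 above, cholesterol genes 15 and glycolysis genes 11, with the other counts the same. The list test was added after the data were seen.

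Among 13720 genes, edgeR called the MEF response above in 3488 and the HPC-7 response above in 2445, and 1137 of the called genes were also called in opposite directions in the lines. The side with more genes changed with the scaling and the set of genes. RLE factors gave 2771 and 3090, library size alone 3020 and 2883, upper quartile factors 2974 and 2912, DESeq2 2644 and 3002, and genes tested in both lines 2425 and 3244, while the median difference was 0.13 with TMM and 0.005 with RLE. TMM put the MEF response above in 58.8% of calls, RLE in 47.3%. Without HPC-7 Control replicate 1, 2 or 3, MEF was above in 2152, 2182 or 2139 genes and HPC-7 in 3343, 3276 or 3314.

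**Figure D4:**
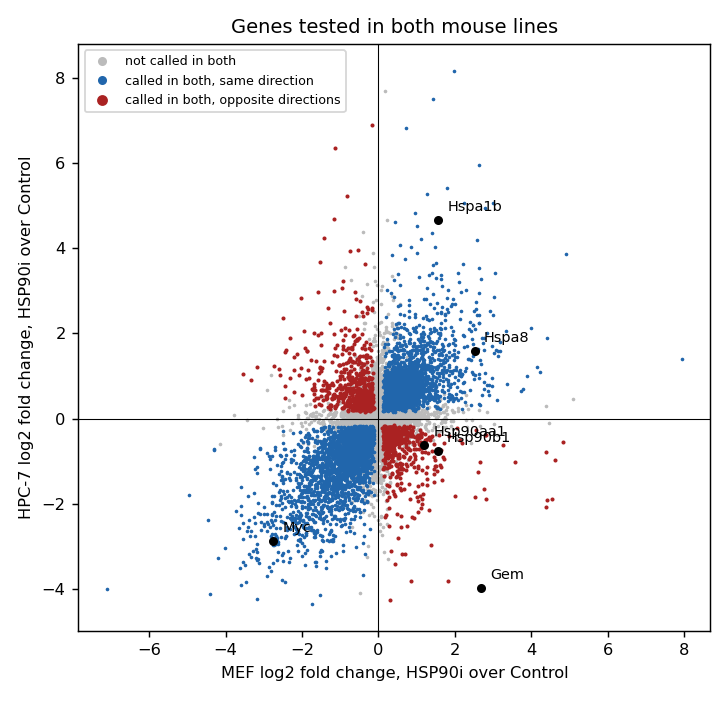
Log2 fold change of HSP90i over Control in MEF (x axis) and HPC-7 (y axis), with a point for each of the 10371 genes tested in both lines, coloured by whether they were called in both and in which direction. Hsp90aa1 and Hsp90b1 lie to the right of 0 and below it, and Pearson's r across genes was 0.55.

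The K562 HSP90 peak list held 801 peaks, with no replicate and no test between samples. Its chromosome and contig names belong to GRCh38, and the fold enrichments are those of the authors' peak caller. Peaks were 213 to 809 bases wide (median 284), with fold enrichments of 1.69 to 38.1 (median 6.71). The strongest peak lay on chromosome 2 at 233725048 to 233725454 (fold 38.1), followed by chromosome 2 at 216109082 to 216109408 (19.7), chromosome 4 at 119454539 to 119454900 (17.8) and chromosome 4 at 121801171 to 121801533 (17.0). The next strongest were on chromosome 19 at 3762782 to 3763161 (16.6), chromosome 3 at 128879335 to 128879700 (15.8) and chromosome 12 at 66057598 to 66057816 (15.5). Chromosome 19 at 5622835 to 5623163 (14.0) and at 4328340 to 4328721 (13.9) and chromosome 7 at 43577489 to 43577785 (13.6) completed the top 10. Chromosome 1 held 99 peaks, chromosome 19 held 79 and chromosome 7 held 57. Genes at these positions were not analysed here.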

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

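The comparison of heat shock genes with the spread of all effects was chosen only after the result was seen, as were the list tests of the interaction. Each result here is a difference between cell lines in the response to the inhibitor, tested as the interaction of line and condition unless said otherwise.

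The MEF response lay above that of HPC-7 in 3488 genes and below it in 2445, by edgeR's quasi-likelihood test. Of 100 regroupings of the condition labels within lines, the real one included, 1 gave as many calls, and the highest of the others gave 3873. The real labels thus gave more calls than any other regrouping drawn, and 1 of 100 is the smallest share this test can give. The other regroupings also broke up the response that the lines share, so they do not stand for equal responses. For that reason the test cannot exclude chance. The split between MEF and HPC-7 changed sides with the scaling, as described in the report.

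The largest differences by the fixed rule, as log2 MEF minus HPC-7 ± SE, mostly involved genes near the floor in the less expressing line. Aldh3a1 (7.12 ± 2.09) had 1 and 0 counts in HPC-7 controls and treated libraries, and its call was lost without HPC-7 Control replicate 2 with an adjusted p near 1 in edgeR's quasi-likelihood test. Gem (6.79 ± 0.52) went from 8.64 to 56.5 CPM in MEF and from 302 to 19.6 CPM in HPC-7. Gap43 (5.77 ± 0.52) had 72 counts in HPC-7 controls and 4 after treatment, Cdon (5.41 ± 0.49) had 45 and 2, and Vipr2 (5.50 ± 0.34) had 7 and 206 in MEF. Among genes with a higher response in HPC-7, Sema7a (−7.88 ± 0.75) had 2 and 13 counts in HPC-7. Il7r (−7.54 ± 1.74) had 3 and 0 counts in MEF, and Itgam (−7.43 ± 1.33) had 10 and 0. Jam3 (−7.40 ± 0.68) had 0 and 72 counts in HPC-7 and Chst1 (−7.27 ± 1.38) had 0 and 15. Where a group was at 0 the fitted difference depends on the prior count and sets no bound.

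Among the fixed genes, differences were called for Hsp90aa1 (1.95), Hsp90ab1 (0.70), Hsp90b1 (2.44), Trap1 (1.45), Hspa1a (−2.76), Hspa1b (−2.98), Hspa8 (1.04), Bag3 (0.54), Hsph1 (0.96) and Hcfc1 (0.62). They come from the joint TMM scaling, whose median difference was 0.13, so small ones may lean towards MEF. The Bag3 call was lost without HPC-7 Control replicate 1, 2 or 3 (adjusted p = 0.0544, 0.0680 and 0.102, edgeR's quasi-likelihood test). By camera, in a separate TMM scaling over genes tested in both lines, lists differed by a median of 0.51 (heat shock), 0.70 (ER chaperones), 0.55 (proteasome), −0.32 (G2/M and mitosis), 0.72 (cholesterol), 0.34 (glycolysis and hypoxia) and −1.11 (SRF and YAP targets). No list held with an estimated correlation (lowest adjusted p = 0.138). Between K562 and HPC-7, every treated library lay above the controls in K562 and below them in HPC-7 for HSP90AA1 (difference 3.83) and HSP90B1 (2.15). These differences between species were not tested.

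Heat shock genes had a median of 2.38 in K562, 0.71 in MEF and 0.14 in HPC-7, which received the lowest dose. A weaker overall response to that dose was tested with the SD of effects after error variance was subtracted. In HPC-7 it was 1.04 times that in MEF, so the spread of effects over all genes was no smaller in HPC-7. K562, at the highest dose, had the highest heat shock median but the smallest SD (0.41, against 0.90 in MEF and 0.94 in HPC-7). Across lines the SD thus followed neither the dose nor the heat shock genes. It cannot tell a weaker response to a dose from a full one. A weaker overall response, a dose too low for heat shock genes alone, the cell line and the time of sampling stay open. Each line had a single dose and time.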

How the results depend on the processing

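The limma-voom sample weights, the residual covariate and the interaction over genes tested in both lines were chosen only after the results were seen. The K562 counts of 688 higher and 803 lower were the least stable. Library size alone gave 435 and 1195, sample weights 2742 and 2849, with a weight of 0.0966 for Control replicate 1, and the residual covariate 3168 and 2910. The covariate gave 4739 and 4951 in MEF and 4410 and 4441 in HPC-7. All 1491 main K562 calls were among its calls in the same direction, but a covariate taken from the residuals of the same data can overstate calls. Leaving out 1 library gave 173 to 1922 higher and 171 to 1995 lower, the highest values being those without Control replicate 1 and the lowest those without HSP90i replicate 1 (higher) and 2 (lower). Fits with a library left out have fewer samples, and otherwise the cause was not tested. In MEF the range was 4003 to 4661 higher and 4304 to 4656 lower, and in HPC-7 3935 to 4358 and 3993 to 4423. Without single libraries 52 of 121 named K562 results changed their call, 2 of 121 in MEF and 4 of 125 in HPC-7, and under the other settings 20, 3 and 4 did, none with a change of direction. The cytosolic ribosomal protein list in K562 had a median of 0.24 without Control replicate 1 and −0.23 without Control replicate 3, both past the threshold in opposite directions.

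Settings other than a left-out library changed 1 list per line. ATF4-CHOP in K562 (adjusted p = 0.0166), NRF2 in MEF (adjusted p = 0.0391) and immediate early genes in HPC-7 (adjusted p = 0.0330) passed camera's threshold with no filter on low counts. The interaction had MEF above in 2139 to 3711 genes and HPC-7 above in 2246 to 3343 when 1 library was left out, the cause of which was not tested. At an adjusted p of 0.01, shared genes numbered 90 higher and 75 lower for K562 and MEF and 62 and 55 for K562 and HPC-7. At 2-fold or more they numbered 343 and 758 for MEF and HPC-7, 46 and 68 for K562 and MEF, and 31 and 35 for K562 and HPC-7. These thresholds pass fewer genes by construction.

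The labels state no pairing of replicate numbers, and same-numbered libraries did not deviate together throughout either mouse line. Same-numbered Control and HSP90i libraries correlated in their deviations by 0.28, 0.04 and 0.45 in K562, 0.27, −0.22 and −0.25 in MEF, and 0.01, 0.02 and −0.09 in HPC-7. With the replicate block, calls numbered 872 higher and 938 lower in K562, 4208 and 4588 in MEF, 4053 and 4076 in HPC-7, and 3195 and 2263 for the interaction. In K562 the block gave more calls than the main 688 and 803, and same-numbered correlations were all positive. Pairing is therefore not excluded in K562. In HPC-7 the block lost Hcfc1 (adjusted p = 0.0826) and mt-Cytb (adjusted p = 0.0804) by edgeR's quasi-likelihood test. By the same test it lost VLDLR, CTH, LSS and MAP1LC3B in K562 (adjusted p = 0.05003, 0.0504, 0.0523 and 0.0631). WDR5 and CSF3R gained a call there (adjusted p = 0.0479 and 0.0405, same test). The planned results on peaks at gene starts were not run, because no human annotation was used here.

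For the HSP90 peaks, median fold enrichment was 8.04 among peaks with at least the median score, against 6.71 for all.

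Simulated 1.5-fold changes were recovered in 26.9% of genes in K562, 70.1% in MEF and 80.6% in HPC-7. The simulation used each line's trended spread and depth together but no shift shared by a whole library. It also changed far fewer genes than were called in the real data, and recovery depends on that share. Recovery in the real libraries may therefore differ.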

Other observations

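The tests of STAT5 targets, of the residual covariate, of Control replicate 1, of the sizes of effects and of the cholesterol genes in HPC-7 HSP90i replicate 2 were chosen only after the results were seen. The FOXO test was set before its result was seen, except its minimum of 5 members, which was added afterwards.

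Genes known as targets of STAT5, a transcription factor activated by cytokine receptors and by BCR-ABL1, were lower in K562 in 9 of 10 tested members, with 0 higher (median −2.78). Beside CISH, SOCS2, PIM1 and ID1, they included PIM2 (−3.07), SOCS3 (−2.46) and SOCS1 (−2.50), named after their values were seen, as are the other genes of this part. In MEF 2 of 10 were higher and 7 lower (median −1.09), and in HPC-7 2 of 9 were higher and 3 lower. CISH fell by 4.62 in K562 and its mouse counterpart rose by 1.35 in HPC-7, a difference that was not tested. Since 7 members were seen before the list was written, the hypothesis that STAT5 targets fall together was tested on the other members, of which only 3 were tested. Camera, which compares a list with the other genes and is no exact test over samples, gave an unadjusted p of 0.00471 in K562, 0.443 in MEF and 0.661 in HPC-7. With an estimated correlation the K562 p was 0.0462 (0.185 adjusted over 12 tests), and over all 10 members the adjusted value was 0.0581. These members are too few to decide it, so a loss of STAT5 signalling in K562 may be worth a direct test and is not established here.

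Genes known as targets of FOXO factors, which growth-factor signalling through AKT keeps out of the nucleus, were higher in 6 of 22 members in K562 (1 lower), 15 of 21 in MEF (4 lower) and 17 of 20 in HPC-7 (3 lower). CCNG2 rose by 1.46 in K562, and its counterpart by 1.92 in MEF and 1.49 in HPC-7. PIK3IP1 rose by 1.23, 1.80 and 2.83. BCL2L11 went the other way in K562 (−1.35) from MEF (2.10) and HPC-7 (1.02), and Klf6 fell in MEF (−2.24). On members not seen first, camera gave an unadjusted p of 0.0169 in K562, 0.0469 in MEF and 0.00266 in HPC-7. Adjusted over 12 tests these were 0.0289, 0.0625 and 0.00637. With an estimated correlation the p was 0.374, 0.101 and 0.123, so a joint rise of FOXO targets may be no more than correlated genes and stays a hypothesis.

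K562 had 1491 calls against 9057 in MEF and 8557 in HPC-7. Mouse libraries thinned to the K562 totals gave at least 8346 calls, which argues against depth, and K562 had 3917 without Control replicate 1 against at least 7928 in mouse fits with 1 library left out, which argues against that library as the whole cause. With the first residual component as a covariate in every line K562 had 6078 calls, MEF 9690 and HPC-7 8851, within the 1.5 times set for this test by a small margin. A wider spread among the K562 libraries may thus account for part of the lower count, although such a covariate can overstate calls and a gap stayed. It did not account for smaller effects, since after error variance was subtracted the SD of K562 log2 fold changes was 0.453 times the smaller mouse SD (0.41, 95% bootstrap interval 0.39 to 0.43, against 0.90 in MEF and 0.94 in HPC-7), and differences of line, species and dose stay open and untested.

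HSP90i replicate 2 of HPC-7 lay nearer to the controls, and thinning the other treated libraries to its depth closed −0.569% of the gap on the first principal component, which argues against depth. A share of untreated-like RNA of 16.7% (95% bootstrap interval 16.0 to 17.3) would be needed by genes at least 4-fold lower and 20.5% (19.4 to 22.4) by genes at least 4-fold higher. The ratio was 0.815, within the 1.5 times set beforehand although the intervals did not overlap. These 4-fold genes had an average log2 CPM of at least 3, while list members were taken at 2-fold lower or beyond with no minimum level. Of 5 lists examined, lowered cholesterol genes needed the least, 8.97% (5.95 to 11.3), against 13.8% for immediate early genes, 14.3% for G2/M, 18.4% for G1/S and 19.8% for ribosome biogenesis. The interval of the cholesterol genes, the extreme of these lists, lay below that of the 4-fold lower genes. These intervals resampled genes rather than libraries, and genes of a pathway can move together, so they may be too narrow. They cannot decide whether such a mixture was the whole cause for the cholesterol genes. A mixture may account for part of the difference, and a weaker response in that sample was not tested.

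With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In K562 the real split gave 1491 calls and the highest of the other splits 1, in MEF 9057 and 0, and in HPC-7 8557 and 0. The number of splits with as many calls was 1 in each line. Every other split mixes treated and control libraries, so the response itself widens the spread within its groups. The low counts of those splits are therefore no measure of false calls.

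Replicate libraries differed by more than sampling noise in every pair, with a chi-square per degree of freedom from 2.31 upwards, so no library was counted as a duplicate. K562 Control replicate 1 differed from Control replicates 2 and 3 by 39.8 and 50.3, which differed from each other by 5.03. In the peak list, 15 peaks on unplaced contigs had a median fold of 2.90 and 13 on chromosome 21 below 8.5 Mb a median of 2.24. The median was 6.74 for 773 peaks elsewhere.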
